A study of Mus musculus with 9 samples.

How the data were processed

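The series measured RNA in mouse embryonic fibroblasts, primary connective tissue cells, that carry a floxed Carm1 gene and a Cre recombinase fused to an estrogen receptor domain. Carm1 encodes an arginine methyltransferase that acts on histones and transcriptional coactivators. The 9 libraries fall into 3 groups of 3 by the labels. WT libraries came from cells with no treatment, KO libraries from cells given 2 uM 4-hydroxytamoxifen (4-OHT) for 6 days, which activates the recombinase and deletes the floxed part of Carm1, and CARM1i libraries from cells given 1 uM TP-064, an inhibitor of the enzyme, for 6 days. No group received 4-OHT without a floxed gene, and no group is labelled as vehicle, so 4-OHT goes with the deletion and any vehicle goes with the inhibitor. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

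Per the labels, the libraries were made with a stranded poly(A) mRNA kit. The submitters' processing notes name TopHat2 2.0.10, HTSeq 0.6.0, DESeq 1.18.0 and the genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited a table of read counts divided by size factors, a normalized signal per gene and library, for 16428 genes. Each gene has at least 10 reads in at least 1 library. In each library 100% of the values were whole multiples of the value of 1 read (tolerance 1e-06 of a read). The size factors recomputed from the recovered reads by the median-of-ratios method equalled the inverses of those steps and ran from 0.925 to 1.16. For KO replicate 2 the step is 1.01, too near 1 for an automatic test of whole multiples, which this library did not pass. Totals of recovered reads were 28657018 to 35842771 per library. The most abundant gene took 1.53 to 1.94% of the reads and the top 10 genes took 7.35 to 8.14%. Gene IDs were matched to GENCODE M21, on the same build, for names, positions and biotypes. Of the IDs, 15078 matched with their version, 16413 without it and 15 did not match.

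The design had been fixed for either unit before the data were examined. Since the values are normalized, the test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean value under 10 over the 9 libraries were left out, which left 14560. All 9 libraries entered a single fit with 3 groups and no other term. P-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. Values are given as mean normalized read count ± SD over n = 3 libraries, and log2 fold changes as estimate ± SE from the fit.

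Gene lists, 30 in all, were fixed before the data were examined. Of these, 28 had at least 3 tested members and the lists of mitochondrial transcripts and of erythroid markers had no member among the genes analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01 and, as an alternative, at a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. As a second test, fry called 17 lists in KO against WT, 11 in CARM1i against WT and 14 in CARM1i against KO. Camera at the preset correlation called 11, 11 and 10. Unlike camera, fry does not set a list against the other genes. Genes named in the text follow a rule also fixed in advance. It takes Carm1 in every library, then per comparison the 8 largest rises and 8 largest falls (4 and 4 for CARM1i against KO) among genes past 0.05 whose groups do not overlap and whose mean over the 9 libraries is at least 100, leaving out predicted gene models, Xist and Y-linked genes. It adds up to 4 members of each list by smallest adjusted p, and for the overlap 4 genes in each shared direction by the smaller of their changes plus up to 4 of opposite sign. Some genes that the rule picks are not used here. Other genes are named only where the text says that they were chosen after their values were seen.

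The alternatives were no filter, a mean of at least 50, quantile normalization, rescaling to a common total, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma without the trend, pseudocounts of 0.5 and 10, only the compared groups in the fit, the replicate number as a block, an adjusted p under 0.01, a 1.5-fold minimum, and leaving out each library. Replicates were compared by a chi-square of their recovered reads; it was 2.47 to 8.46 per gene, so no library was a copy of another. The replicate numbers were checked for pairing and treated as names only.

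The fit was tested on simulated counts with the real means, size factors and dispersions, in which 200 genes per group were changed. For KO against WT it recovered 72% of genes changed 1.5-fold and 87% of those changed 2-fold, with 14 of 173 calls on unchanged genes over 14590 genes. For CARM1i against WT these values were 73%, 90% and 12 of 175 calls, and for CARM1i against KO 75.5%, 90.5% and 25 of 357 calls. The overlap of the comparisons that share the WT libraries was set beside 50 simulated data sets with no change.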

Results

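The series holds 9 RNA libraries of mouse embryonic fibroblasts with a floxed Carm1 gene and a tamoxifen-inducible Cre recombinase, 3 untreated (WT), 3 after 4-OHT (KO) and 3 after the inhibitor TP-064 (CARM1i). Totals ran from 28657018 to 35842771 recovered reads per library. The first principal component of the log values, with 42.7% of the variance, placed the WT libraries between -25.4 and -22, the CARM1i libraries between -5.84 and 2.27 and the KO libraries between 25.2 and 27.6. CARM1i replicate 3 stood apart from the other 2 of its group on the third component (9.58% of the variance), at 19.5 against -11 and -11.7.

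Carm1 (ENSMUSG00000032185.15; mm10, chromosome 9, 21546894 to 21592623) was counted over the whole gene. It measured 1079, 1143 and 1091 normalized counts in WT replicates 1 to 3, then 794, 711 and 770 in the KO libraries, and 1112, 1072 and 986 in the CARM1i libraries. The KO mean of 758 ± 43 was 68.7% of the WT mean of 1104 ± 34.1 (log2 fold change -0.54 ± 0.06, adjusted p = 5.493e-07). The CARM1i mean of 1057 ± 64 differed from WT by less than the test could call (-0.06 ± 0.06, adjusted p = 0.496). The counts do not separate the floxed exons from the rest of the transcript. They do not show how much of the KO value came from outside the deleted part, and so do not check the deletion.

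**Figure D1:**
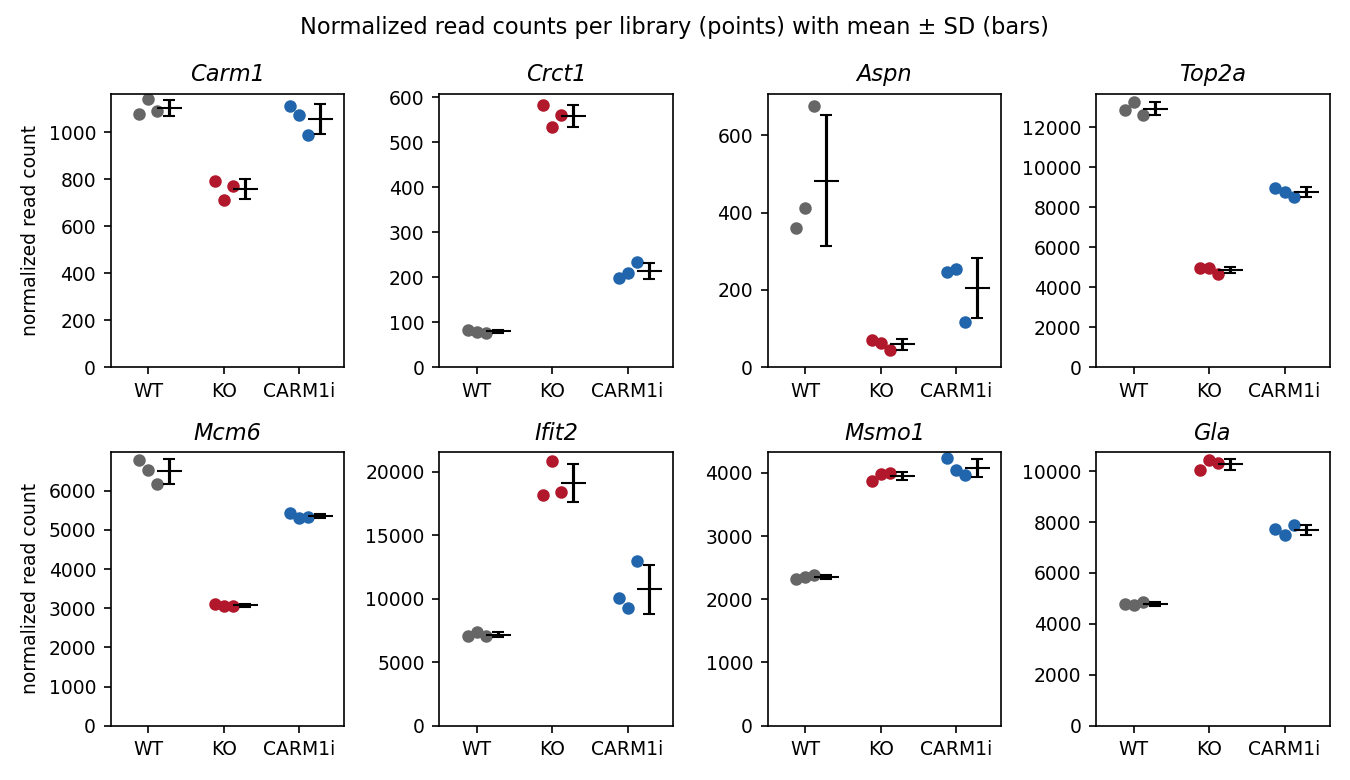
Normalized read count (vertical axis, from 0) of 8 genes in each library by group, with points for the 3 libraries and bars for mean ± SD. Carm1 was lower in the 3 KO libraries than in the other 6, Aspn, Top2a and Mcm6 fell and Crct1, Ifit2 and Gla rose more in KO than in CARM1i, and Msmo1 stood at similar levels in KO and CARM1i.

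The first comparison asked what changes in fibroblasts after 4-OHT deletes Carm1. All 24 mitosis genes and 22 of 24 S phase genes fell, and 24 of 26 interferon-stimulated, 23 of 25 sterol synthesis and 21 of 27 autophagy and lysosome genes rose. With an estimated correlation only the mitosis and the autophagy and lysosome lists were called, and the adjusted p was 0.09228, 0.2884 and 0.2869 for the S phase, interferon and sterol lists. Crct1, a gene of the epidermal differentiation cluster (ENSMUSG00000027913.5; chromosome 3, 93014205 to 93015687), went from 79.6 ± 3.47 in WT to 559 ± 24.1 in KO, a 6.95-fold rise (adjusted p = 5.148e-13). Ivl, which encodes the cornified envelope protein involucrin on the same chromosome (92570902 to 92573735), rose 3.88-fold from 795 ± 23.6 to 3088 ± 115. Nptx1, a neuronal pentraxin, rose 6.22-fold (34.9 ± 6.94 to 221 ± 27.9) and Acod1, the itaconate-producing enzyme of activated macrophages, rose 5.06-fold (41.1 ± 11.6 to 207 ± 2.66). Hsd11b1, which regenerates active glucocorticoid, rose 4.07-fold and the chemokine Ccl8 rose 4.06-fold to 1847 ± 61.9. The interferon-inducible Ifi207, which has near-identical neighbours that can share its reads, rose 3.74-fold, and Aldh1l1, an enzyme of folate metabolism, 3.71-fold.

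The largest fall by the rule was that of Aspn, a small matrix proteoglycan (ENSMUSG00000021388.14; chromosome 13, 49544443 to 49567565), from 483 ± 170 to 59.6 ± 14.1, a log2 fold change of -2.97 ± 0.26 (adjusted p = 4.847e-08). Cxcl5, a neutrophil chemokine, fell by 2.45 ± 0.23 on the log2 scale, from 605 ± 170 to 107 ± 12.8, and the Wnt antagonist Dkk2 by 2.21 ± 0.15. The other 5 were replication-dependent histone genes of the chromosome 13 cluster. The linker histone gene Hist1h1b went from 5371 ± 346 to 1194 ± 85.1 (log2 fold change -2.17 ± 0.06), Hist1h2bh from 2443 ± 181 to 564 ± 7.06 (-2.11 ± 0.06), Hist1h1a from 931 ± 62.2 to 199 ± 12.9 (-2.22 ± 0.08), Hist1h2ae from 716 ± 42.5 to 155 ± 12.7 (-2.20 ± 0.10) and Hist1h2an from 317 ± 22.7 to 65.6 ± 16.8 (-2.28 ± 0.17). Genes of this family share near-identical sequence, and most of their transcripts end without a poly(A) tail, so single values are uncertain in a poly(A) library.

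All 24 mitosis genes fell in KO, with a median log2 fold change of -1.13. Top2a, which untangles chromosomes, went from 12914 to 4855 (-1.41 ± 0.03), the cyclin gene Ccna2 went from 2641 to 935, the spindle motor gene Kif11 fell by 1.46 ± 0.05 and the proliferation marker Mki67 by 1.48 ± 0.05. Of the 24 S phase genes, 22 fell and 2 did not pass, with a median of -0.82. Mcm6, of the replicative helicase, went from 6493 to 3076, the ribonucleotide reductase subunits Rrm1 and Rrm2 fell by 1.10 and 1.24, and Uhrf1 by 1.13. The mitosis list was called with an estimated correlation too (adjusted p = 0.04962), and the S phase list was not (adjusted p = 0.09228 with an estimated correlation). Of 23 p53 targets, 13 rose and 2 fell (median 0.17). Trp53inp1 rose by 0.66 ± 0.04, Mdm2, the ubiquitin ligase that restrains p53, by 0.65 ± 0.05 and Ccng1 by 0.39 ± 0.04, while Ckap2, also a mitotic spindle gene, fell by 0.72 ± 0.05. The p53 list's adjusted p was 0.2884 with an estimated correlation.

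Interferon-stimulated genes rose in KO in 24 of 26 cases and none fell (median 0.48). Ifit2 went from 7179 to 19143 (1.41 ± 0.08), Ifit3 from 20648 to 44413 (1.10 ± 0.08), Ifit1 rose by 0.81 ± 0.06 and Cmpk2 by 1.27 ± 0.09. The list's adjusted p was 0.2884 with an estimated correlation. Of 25 sterol synthesis and uptake genes, 23 rose, and 25 when adjusted over the list alone (median 0.50). Msmo1, a sterol demethylation enzyme, went from 2356 to 3951 (0.75 ± 0.03), Fdft1 rose by 0.63 ± 0.04 and Lss by 0.70 ± 0.05, with an adjusted p of 0.2869 with an estimated correlation for the list. Among 27 autophagy and lysosome genes, 21 rose and 1 fell (2 fell when adjusted over the list alone or without CARM1i replicate 3), with a median of 0.44. The lysosomal hydrolase genes Gla (4784 to 10263), Hexa (6795 to 12882) and Ctsd (11930 to 20561) rose by 1.10, 0.92 and 0.79 on the log2 scale, and the list was called with an estimated correlation (adjusted p = 0.04962). Of 19 NRF2 targets 13 rose and 2 fell (median 0.33). The iron store gene Fth1 rose by 0.86 ± 0.04, the heme oxygenase gene Hmox1 by 0.88 ± 0.04, Taldo1 by 0.44 ± 0.03 and Ephx1 by 0.40 ± 0.04 (adjusted p = 0.2884 with an estimated correlation for the list). In the same libraries the macrophage marker Cd68 rose from 42.5 to 86 and Cd14 fell from 147 to 109, while Mrc1 (0.31 ± 0.22) and Csf1r (0.17 ± 0.21) did not pass. The call of Cd14 ended without WT replicate 2 or without KO replicate 2 or 3. Of 15 myeloid genes, chosen after the gene tables were seen, 9 rose in KO and none fell. Their median was 1.22, and the list's adjusted p was 0.0849 with an estimated correlation.

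Matrix genes went both ways in KO. Of 30 collagen and matrix genes, 17 fell and 8 rose (median -0.30). Col3a1 went from 5969 to 2471 (-1.27 ± 0.06), Col6a3 fell by 1.33 ± 0.08 and Col1a1 went from 23155 to 12075, while Postn, the matricellular protein periostin, rose from 5572 to 9765 (0.82 ± 0.06). The list's adjusted p was 0.7056 with an estimated correlation. Contractile and TGF-beta responsive genes fell in 13 of 23 cases and rose in 4 (14 and 5 when adjusted over the list alone), with Ccn1 at -0.35 ± 0.04, Id1 at -0.35 ± 0.04, Tpm1 at -0.23 ± 0.03 and Tgfbi at -0.70 ± 0.10 (adjusted p = 0.4153 with an estimated correlation for the list). Ribosomal protein genes fell in 27 of 30 cases and none rose (28 fell when adjusted over the list alone), by small amounts (median -0.15), with Rpl3 at -0.36 ± 0.03 and Rpl27 at -0.23 ± 0.03. The adjusted p was 0.3278 with an estimated correlation. Of 16 chaperones of the endoplasmic reticulum, 9 fell and 1 rose (median -0.15), among them Pdia6 at -0.31 ± 0.03 and Herpud1 at -0.35 ± 0.05 (adjusted p = 0.4594 with an estimated correlation for the list).

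The remaining lists were not called by camera in KO. Of them, fry called the methyltransferase (adjusted p = 0.0004746), adipocyte (0.0003675), glycolysis and hypoxia (0.0003675), neural (0.0001144), endothelial (0.01629), cartilage (0.02698) and inflammatory (0.04386) lists. The methyltransferase list holds Carm1, the gene deleted in KO, so the design favours its call. Of the lists that camera called, fry did not call collagen and matrix (adjusted p = 0.06339). In the arginine methyltransferase family, Prmt2 rose by 0.22 ± 0.04 while Carm1, Prmt1 (-0.19 ± 0.04) and Prmt7 (-0.22 ± 0.05) fell and 4 did not pass. Of 16 histone acetyltransferases and coactivators, Hat1 (-0.60 ± 0.06), Kat7 (-0.22 ± 0.04) and Kat2a (-0.13 ± 0.04) fell and 13 did not pass. Of 16 deacetylases and corepressors 3 rose and 2 fell, with Sirt2 at 0.49 ± 0.04 and Hdac7 at -0.54 ± 0.05. Among 22 CREB and immediate early targets 8 rose and 5 fell, with Ier3 at 0.50 ± 0.04 and Sik1 at -0.50 ± 0.07. Of 23 inflammatory genes 10 rose and 5 fell, including Ccl7 at 0.49 ± 0.04 and the chemokine gene Cxcl12 at -0.91 ± 0.09. Of 13 adipocyte genes 6 rose and 3 fell, with Plin4 from 217 to 575 and the platelet-derived growth factor receptor gene Pdgfra from 38495 to 23991. ATF4 targets split into 5 higher and 10 lower of 25 (5 and 11 when adjusted over the list alone), with the stress factor gene Ddit3 at 0.57 ± 0.04, and glycolysis and hypoxia genes into 8 higher and 4 lower of 21 (9 and 5 when adjusted over the list alone), with Vegfa from 7242 to 11426. Of 8 xenobiotic receptor targets 2 rose and 4 fell, with the sterol exporter gene Abca1 from 1103 to 485 and Abcg1 from 65.5 to 19.4. Hox genes had 2 higher and 3 lower of 19. Beside 41.9% of all tested genes, some markers of other cell types passed. They were 1 of 4 endothelial (Egfl7, 0.35 ± 0.12), 1 of 3 epithelial (Krt18, 38 to 112), 1 of 4 skeletal muscle (Acta1, 152 to 234) and 1 of 3 cartilage markers (Sox9, 0.32 ± 0.09), all higher, and 3 of 6 neural markers, all lower (Nes 510 to 260, Tubb3 109 to 36.1, Ncam1 7097 to 5681). None of the 4 tested sex-linked genes passed under limma, adjusted over all genes or over the list alone, and the lowest adjusted p was 0.05393 (Eif2s3y). Eif2s3y passed with a mean of at least 50, with quantile normalization (adjusted p = 0.02097), rescaled to a common total, with only the compared groups, and without WT replicate 3 or KO replicate 2; 1 of the 4 genes passed without CARM1i replicate 3. In every comparison, counts adjusted over the list alone equalled those over all genes for the lists where none is given. The acetyltransferase, immediate early and xenobiotic receptor lists had a median of another sign than their mean and test in KO.

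In all, 6100 of 14560 genes passed in KO against WT, 3114 higher and 2986 lower, and 7123 had an unadjusted p under 0.05. Rescaled to a common total, 2837 were higher and 3286 lower. Most changes were small, with 196 genes at least 2-fold higher and 344 at least 2-fold lower, and 1436 past 0.05 with at least a 1.5-fold change. The calls of Egfl7, Kat2a and Hoxb7 ended in at least 1 fit without a library, and that of Acta1 without the intensity trend. 4-OHT and the deletion cannot be separated in this comparison. Of the 28 lists, 11 were called at the preset correlation and 2 with an estimated correlation.

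The second comparison asked what the inhibitor changes in the same cells with the gene intact. All 24 mitosis genes and 18 of 24 S phase genes fell, and 23 of 25 sterol synthesis and 19 of 27 autophagy and lysosome genes rose. With an estimated correlation the adjusted p was 0.1901 for the S phase list and 0.06303 for the sterol list. Crct1 rose 2.65-fold to 213 ± 18.1, the leukocyte integrin gene Itgb2 (ENSMUSG00000000290.13; chromosome 10, 77530252 to 77565708) rose 2.34-fold from 71.4 ± 14.5 to 168 ± 28.4, and Nptx1 rose 2.31-fold to 86.6 ± 41.2. Hsd11b1 rose 2.27-fold, Ccl8 2.23-fold, Tm7sf2, a sterol reductase gene, 2.08-fold, Aldh1l1 2.06-fold and Ifi207 2.05-fold. Aspn fell to 205 ± 77 (-1.26 ± 0.26) and Cxcl5 to 270 ± 105 (-1.21 ± 0.23). The Notch ligand gene Jag1 (ENSMUSG00000027276.7; chromosome 2, 137081456 to 137116644) went from 328 ± 35.7 to 154 ± 12.5 (adjusted p = 5.463e-06). The netrin receptor gene Unc5c fell from 162 ± 18.4 to 84.4 ± 17.8, the adhesion molecule gene Mcam from 200.1 ± 32.7 to 108 ± 27.6, Txnip, which restrains glucose uptake, from 1811 ± 43.5 to 976 ± 60, C1qtnf3 from 729 ± 154 to 391 ± 66.7 and Hist1h2an from 317 ± 22.7 to 171 ± 35.9. Without the intensity trend Aspn (adjusted p = 0.06931) and Cxcl5 (adjusted p = 0.05526) missed the threshold.

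All 24 mitosis genes also fell in CARM1i (median -0.52). Top2a fell by 0.56 ± 0.03 to 8752, Kif20a by 0.54 ± 0.04, Kif11 by 0.58 ± 0.05 and Cdk1 by 0.45 ± 0.04, and the list was called with an estimated correlation (adjusted p = 0.04117). Of 24 S phase genes 18 fell, and 20 when adjusted over the list alone (median -0.23), with Rrm1 at -0.42 ± 0.04 and Mcm6 at -0.28 ± 0.04. The adjusted p was 0.1901 with an estimated correlation. Of 25 sterol synthesis genes 23 rose, and 25 when adjusted over the list alone, with a median of 0.64. Msmo1 rose to 4082 (0.79 ± 0.03) and the feedback regulator Insig1 by 0.87 ± 0.05 (adjusted p = 0.06303 with an estimated correlation for the list). Interferon-stimulated genes rose in 22 of 26 cases, 24 when adjusted over the list alone. Their median was 0.27, and 0.19 without CARM1i replicate 3. Cmpk2 stood at 0.70 ± 0.09, Mx1 at 0.71 ± 0.09, Usp18 at 0.31 ± 0.04 and Ifit1 at 0.40 ± 0.06. The adjusted p was 0.2271 with an estimated correlation. None of the 4 macrophage markers passed under limma, and the lowest adjusted p was 0.4077 (Mrc1, 0.29 ± 0.22), while of 15 myeloid genes, chosen after the gene tables were seen, 7 rose and none fell (median 0.65; adjusted p = 0.07821 with an estimated correlation). Autophagy and lysosome genes rose in 19 of 27 cases and 1 fell (20 and 1 when adjusted over the list alone), with Gla at 7707, Hexa at 10357 and a median of 0.20, and the list was called with an estimated correlation (adjusted p = 0.04117). NRF2 targets rose in 11 of 19 cases and 1 fell (12 and 2 when adjusted over the list alone), with Fth1 at 0.45 ± 0.04, Hmox1 at 0.50 ± 0.04 and Tkt at -0.41 ± 0.04 (adjusted p = 0.2271 with an estimated correlation for the list).

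Collagen and matrix genes fell in 15 of 30 cases in CARM1i and rose in 3 (16 and 4 when adjusted over the list alone, and 5 rose past 0.05 over all genes without CARM1i replicate 3). Col8a1 fell by 0.39 ± 0.04, Col5a1 by 0.43 ± 0.05, Col3a1 by 0.48 ± 0.06 and Col1a1 by 0.45 ± 0.06, with an adjusted p of 0.6071 with an estimated correlation for the list. Contractile and TGF-beta responsive genes fell in 10 of 23 cases and 1 rose (none without CARM1i replicate 3 under limma); Ccn2 fell by 0.47 ± 0.05, Acta2 by 0.32 ± 0.04 and Tpm1 by 0.30 ± 0.03 (adjusted p = 0.2271 with an estimated correlation). Adipocyte genes rose in 5 of 13 cases and none fell (1 fell when adjusted over the list alone), with Fasn at 0.30 ± 0.03 and Scd1 at 0.35 ± 0.04 (adjusted p = 0.1883 with an estimated correlation). Glycolysis and hypoxia genes had 6 higher and 2 lower of 21 (7 and 2 when adjusted over the list alone), with Vegfa at 0.44 ± 0.03 and Hk2 at 0.45 ± 0.04 (adjusted p = 0.4111 with an estimated correlation). Ribosomal protein genes fell in 11 of 30 cases, 17 when adjusted over the list alone, and in 19 without CARM1i replicate 3; Rpl3 stood at -0.16 ± 0.03, and the list's adjusted p was 0.4111 with an estimated correlation.

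Other lists were not called by camera in CARM1i. Of them fry called the neural list (adjusted p = 0.01417), and of the lists that camera called it did not call collagen and matrix (adjusted p = 0.1558). Of 23 p53 targets 2 rose and 5 fell, with Mdm2 at 0.22 ± 0.05, Ckap2 at -0.56 ± 0.05 and the death receptor gene Fas at -0.57 ± 0.11. ATF4 targets had 4 higher and 2 lower of 25 (Ddit3 0.26 ± 0.04), and inflammatory genes 6 and 6 of 23 (Il1rl1 0.38 ± 0.04, Nfkbia -0.39 ± 0.04). Il1rl1 was at 0.19 with quantile normalization. Deacetylases had 3 and 1 of 16 (Sirt2 0.24 ± 0.04), immediate early targets 2 and 1 of 22 (Nr4a1 0.35 ± 0.07) and xenobiotic receptor targets 1 and 2 of 8 (Nfe2l2 0.21 ± 0.03, and 3 lower when adjusted over the list alone). Of the acetyltransferases and coactivators, Hat1 (-0.23 ± 0.06) and Kat2a (-0.12 ± 0.04) fell, 1 of them when adjusted over the list alone, and of the Hox genes Hoxb2 fell (-0.22 ± 0.07; none when adjusted over the list alone, and none past 0.05 without CARM1i replicate 3). Ncam1 and Nes fell among 6 neural markers and Egfl7 rose among 4 endothelial markers. No member passed under limma among the 8 arginine methyltransferases (lowest adjusted p 0.2227, Prmt1), the 16 endoplasmic reticulum chaperones (0.08448, Pdia4), or the tested epithelial, skeletal muscle (1 passed without CARM1i replicate 3), cartilage and sex-linked genes. Of the chaperones, Pdia4 passed without CARM1i replicate 3, and Pdia6 with quantile normalization (-0.12, adjusted p = 0.01302) or rescaling to a common total (adjusted p = 0.03213).

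In all, 2784 of 14560 genes passed in CARM1i against WT, 1533 higher and 1251 lower, with 4482 at an unadjusted p under 0.05. Rescaled to a common total, 1346 were higher and 1510 lower, so which direction held more genes depended on the scaling. Only 33 were at least 2-fold higher and 26 at least 2-fold lower. Single calls of Kat2a, Hoxb2, Egfl7, Rpl27, Hat1, Mdm2, Ier3, Nr4a1 and Abcg1 ended under at least 1 other setting. Mean, median and test differed in sign for the deacetylase, inflammatory, endothelial, epithelial, cartilage and sex-linked lists. The count of lower genes was 806 without WT replicate 2, and the whole count was 1797 without the intensity trend and 281 with at least a 1.5-fold change. Any vehicle of the inhibitor goes with the treatment in this comparison. Of the 28 lists, 11 were called at the preset correlation and 2 with an estimated correlation.

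**Figure D2:**
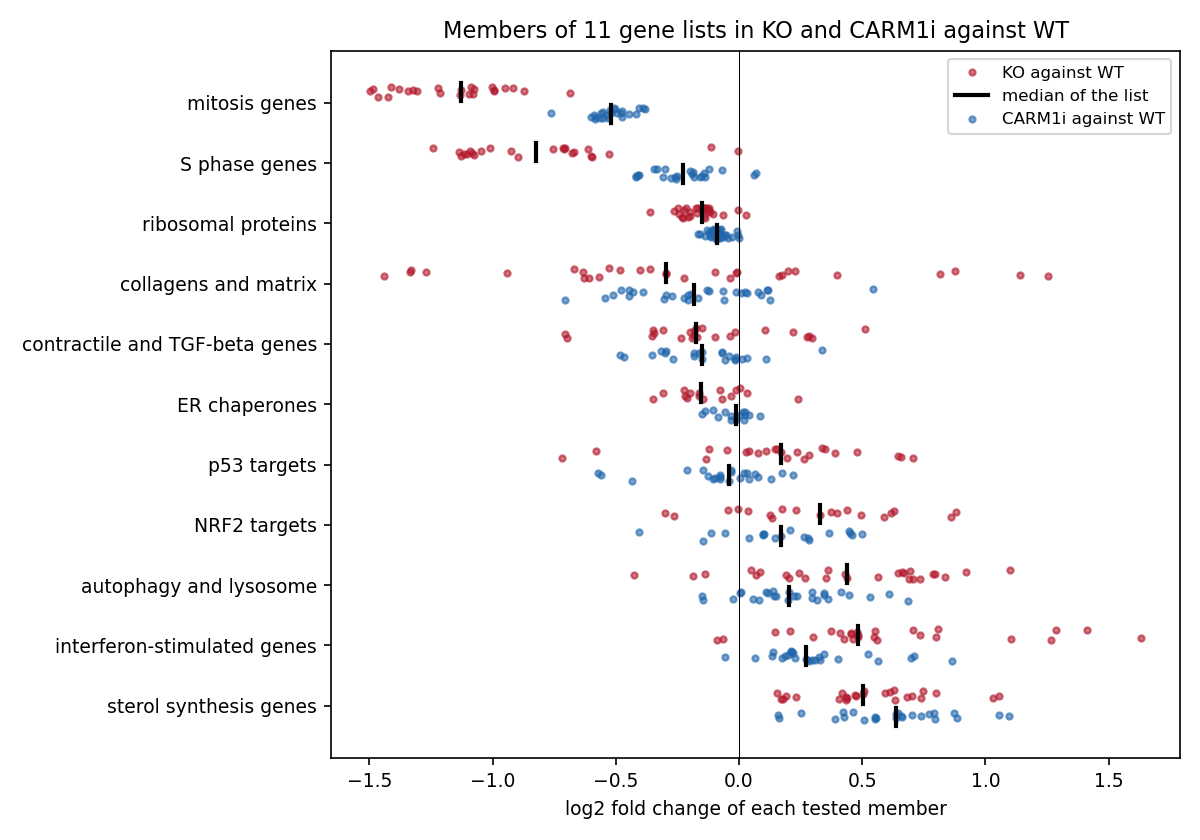
Log2 fold change of each tested member (horizontal axis) of 11 gene lists, in KO against WT (red) and CARM1i against WT (blue); black bars are medians of a list. Mitosis genes sit to the left of 0 in both (medians -1.13 and -0.52) and sterol synthesis genes to the right at similar distances (0.50 and 0.64).

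The third comparison set the CARM1i libraries against the KO libraries and tested where the treatments differ. CARM1i libraries held more of Aspn (log2 fold change 1.71 ± 0.26), Dkk2 (1.52 ± 0.15), Hist1h2ae (1.48 ± 0.10) and Hist1h1b (1.44 ± 0.06), which had fallen in KO, and less of Acod1 (-1.73 ± 0.29), Nptx1 (-1.43 ± 0.24), Crct1 (-1.39 ± 0.10) and Megf10 (-1.32 ± 0.12), a phagocytic receptor gene at 205 ± 24.9 in WT, 684 ± 55.2 in KO and 275 ± 57.2 in CARM1i. All 24 mitosis genes and 23 of 24 S phase genes were higher in CARM1i than in KO (medians 0.62 and 0.62), for example Ccna2 by 1.02 ± 0.04 and Uhrf1 by 0.87 ± 0.04. p53 targets were lower in CARM1i in 15 of 23 cases and higher in 2 (16 and 2 when adjusted over the list alone), with Ccng1 at -0.46 ± 0.04, Trp53inp1 at -0.49 ± 0.04, Mdm2 at -0.43 ± 0.05 and the cell cycle inhibitor gene Cdkn1a at -0.39 ± 0.05. Autophagy and lysosome genes were lower in 19 of 27 cases (20 when adjusted over the list alone), with Ctsd at -0.44 ± 0.03. These 4 lists were called with an estimated correlation (adjusted p = 0.04134 for mitosis, S phase and autophagy and lysosome, 0.04154 for p53 targets).

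Interferon-stimulated genes were lower in CARM1i than in KO in 22 of 26 cases and 1 was higher (23 and 1 when adjusted over the list alone), with Ifit2 at -0.85 ± 0.08. The adjusted p was 0.4929 with an estimated correlation. None of 25 sterol synthesis genes was lower in CARM1i, 7 were higher (8 when adjusted over the list alone) and 18 did not pass; Insig1 was higher by 0.26 ± 0.05 (adjusted p = 0.6813 with an estimated correlation). NRF2 targets were lower in 9 and higher in 2 of 19 (11 and 2 when adjusted over the list alone; Fth1 -0.41 ± 0.04, list adjusted p = 0.4929 with an estimated correlation). Chaperones were higher in 8 and lower in 1 of 16 (9 and 1 when adjusted over the list alone; Pdia6 0.22 ± 0.03, list adjusted p = 0.5097 with an estimated correlation). Inflammatory genes were lower in 10 and higher in 2 of 23 (5 higher without CARM1i replicate 3; Csf1 -0.45 ± 0.04, list adjusted p = 0.5285 with an estimated correlation). Ribosomal protein genes were higher in 11 of 30 (13 when adjusted over the list alone, and 4 past 0.05 over all genes without CARM1i replicate 3; list adjusted p = 0.5285 with an estimated correlation). Lists not called by camera had members past 0.05 in both directions, in a single direction or in none. Of those lists, fry called the methyltransferase (adjusted p = 0.007338), deacetylase (0.02158), neural (0.00355), cartilage (0.02338), endothelial (0.0394) and skeletal muscle (0.04659) lists. The methyltransferase list holds Carm1, the gene deleted in KO, so the design favours its call here too. Of the lists that camera called, fry did not call sterol synthesis (adjusted p = 0.1584) and inflammatory genes (adjusted p = 0.05286). Collagen and matrix genes had 12 higher and 7 lower of 30 (14 and 9 when adjusted over the list alone), with Col3a1 at 0.79 ± 0.06 and Postn at -0.78 ± 0.06. ATF4 targets had 9 higher and 4 lower of 25 (11 and 5 when adjusted over the list alone), immediate early targets 6 and 5 of 22 and contractile and TGF-beta genes 5 and 6 of 23 (6 and 7 when adjusted over the list alone). Deacetylases had 3 and 1 of 16 (3 and 2 when adjusted over the list alone), and xenobiotic receptor targets 3 and 2 of 8 (Abca1 1.04 ± 0.11). Acetyltransferases had 2 and 1 of 16 (Hat1 0.37 ± 0.06), and adipocyte genes 2 and 2 of 13 (Pdgfra 0.58 ± 0.04). Glycolysis and hypoxia genes had 1 and 5 of 21 (3 and 5 when adjusted over the list alone) and arginine methyltransferases 1 and 1 of 8, Carm1 at 0.48 ± 0.06 and Prmt2 at -0.18 ± 0.04 (4 and 1 when adjusted over the list alone). Hoxb4 and Hoxb7 were lower, as were Krt18, Acta1 and Sox9, and the neural markers Nes and Tubb3 were higher. None of the 4 macrophage (lowest adjusted p 0.0568, Cd68), 4 endothelial (0.07585, Cdh5; 3 lower when adjusted over the list alone) and 4 sex-linked genes passed under limma. Cd68 passed under edgeR (adjusted p = 0.03797), DESeq2 (adjusted p = 0.02588), the replicate block, a pseudocount of 10 and without KO replicate 1, Cd14 without KO replicate 1 and Cdh5 without the intensity trend (adjusted p = 0.03759). Without CARM1i replicate 3, 1 macrophage and 2 endothelial markers passed, 1 autophagy and lysosome and 1 Hox gene were higher, glycolysis and hypoxia genes had 2 higher, and no acetyltransferase was lower under limma. The contractile, adipocyte, glycolysis, Hox, macrophage and epithelial lists had a mean, median or test of differing sign. The calls of Hk2 and Kat7 ended under 1 other setting each. Over all genes 3436 passed, 1761 higher and 1675 lower in CARM1i, with 4986 at an unadjusted p under 0.05. With quantile normalization 1717 were higher and 1767 lower. An adjusted p under 0.01 was reached by 2155 genes, and 522 passed with at least a 1.5-fold change.

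The last comparison asked how far the changes of deletion and inhibition coincide. Crct1, Itgb2, Nptx1 and Hsd11b1 led the genes that rose in both by the smaller of their changes, and Aspn, Cxcl5, Jag1 and Hist1h2an those that fell in both. Jag1 was 2.05-fold lower in KO and 2.12-fold lower in CARM1i (adjusted p of the difference 0.8283), while Itgb2 rose by 1.87 ± 0.16 in KO and 1.23 ± 0.16 in CARM1i (adjusted p of the difference 0.006215). In all, 1380 genes rose in both and 1083 fell in both, against 327.9 and 256.6 for independent lists of those sizes, and 16 passed with opposite signs against 581.9. Rescaled to a common total, 1211 rose in both and 1303 fell in both. The genes that fell in both were 701 without WT replicate 2 and 670 without the intensity trend. The genes shared were 90% of those that rose in CARM1i and 86.6% of those that fell. Of the 2463 genes shared in sign, 2157 (87.6%) had the larger change in KO, and 1368 of them differed between CARM1i and KO, 1342 with the larger change in KO and 26 with the larger change in CARM1i. The median ratio of the CARM1i to the KO log2 fold change over the 2463 was 0.589.

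Among genes of opposite sign, Sept4 was at -0.45 ± 0.10 in KO and 0.41 ± 0.10 in CARM1i, the matrix gene Frem1 at -0.39 ± 0.05 and 0.27 ± 0.05, the serotonin receptor gene Htr2a at 0.23 ± 0.06 and -0.22 ± 0.06, and the matrix gene Efemp1 at 0.21 ± 0.06 and -0.21 ± 0.06. Without the intensity trend Sept4, Htr2a and Efemp1 missed the threshold in CARM1i (adjusted p = 0.1, 0.1064 and 0.1483), and so did Efemp1 in KO. Htr2a moved to -0.14 in CARM1i without CARM1i replicate 2 (adjusted p = 0.1226) and Efemp1 to 0.13 in KO without KO replicate 2 (adjusted p = 0.1043), and both missed the threshold in further fits without a library. The genes of opposite sign were 35 without CARM1i replicate 3, 6 without CARM1i replicate 2, 7 without WT replicate 1 or 2, 9 under DESeq2 and 6 without the intensity trend. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.718, and 50 simulated data sets with no change, made against shared controls, gave a mean r of 0.493. The covariance was 0.0792 against a simulated mean of 0.0157, a difference of 0.0635. Those data sets gave at most 1 gene past 0.05 in both in either direction. Since no gene was changed in them, so low a count was set in advance and is no measure of the overlap. They also held no difference of the untreated WT cultures from both treated groups, so they bear only on noise from shared controls. The 3 WT libraries cannot be split with at least 2 in each part, so part of the excess over independent lists may come from the shared controls. With limma without the trend 1607 genes were shared in sign.

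**Figure D3:**
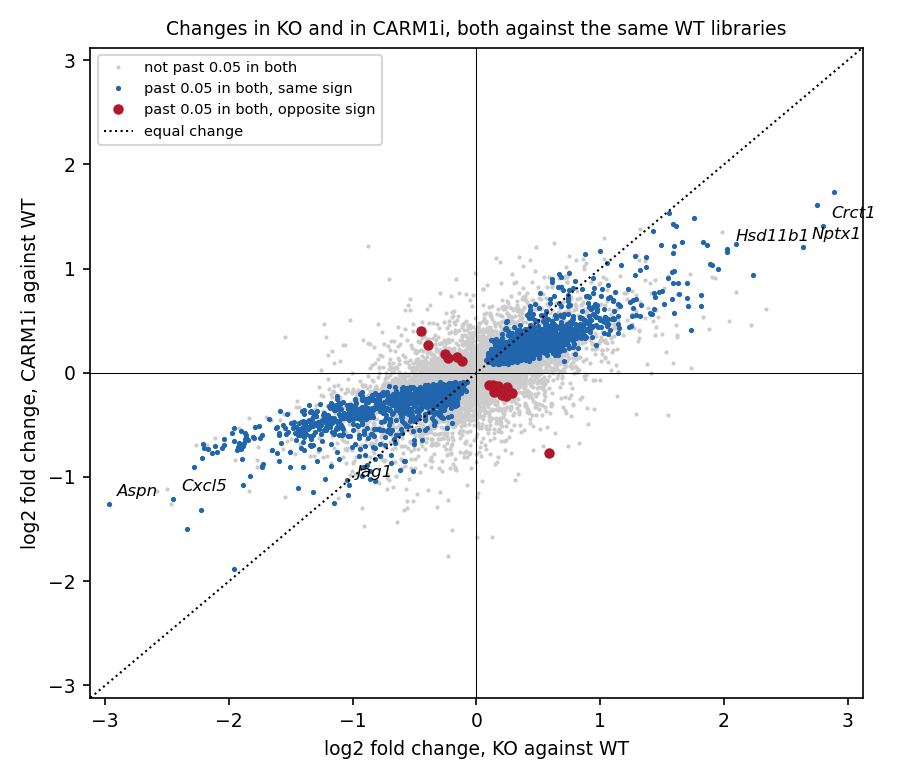
Log2 fold change of each tested gene in KO against WT (horizontal axis) and CARM1i against WT (vertical axis). Blue points are the 2463 genes past 0.05 in both with the same sign, red points the 16 of opposite sign and grey points all others. Most blue points lie between the horizontal axis and the dotted line of equal change.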

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

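The tests of S phase genes, macrophage markers, interferon genes and sterol genes below were chosen only after those results were seen, while those of small RNA genes, the summed histone genes and other splits were written before their values were computed. The lists and genes of the next paragraph are given because the effects of deletion and inhibition, both against WT, differed in the test of CARM1i against KO. The paragraphs after it take up further results. Among them, the interferon and sterol lists did not pass in that test with an estimated correlation (adjusted p = 0.4929 and 0.6813).

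The median difference of CARM1i minus KO was 0.62 for the mitosis list and 0.62 for the S phase list, which fell further in KO, and -0.23 for autophagy and lysosome genes, which rose further in KO. For p53 targets the median difference was -0.21, with medians of 0.17 in KO and -0.04 in CARM1i. Of the 16 genes of opposite sign, the 4 named by the rule had differences of 0.85 (Sept4), 0.66 (Frem1), -0.45 (Htr2a) and -0.42 (Efemp1).

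The fall of histone transcripts in KO covered 54 of 59 tested genes named Hist1h to Hist4h, with a median of -1.76 (-0.58 in CARM1i; list adjusted p = 0.06087 and 0.07821 with an estimated correlation), while Hist3h2a rose (0.34, a call that ended under 9 settings) and 4 did not pass. Unequal carry-over of RNA without a poly(A) tail would also lower other such RNAs, though not necessarily to the same degree. Of 111 tested small nuclear, nucleolar, Cajal body and other small RNA genes, 32 fell and 1 rose in KO, and 9 fell and 1 rose in CARM1i. In KO their lower quartile was -0.69 and their median -0.40, above the histone median divided by 2. That argues against carry-over as the whole cause only if these RNAs are carried over like histone transcripts, which was not tested. A share of the fall from carry-over stays open. Reads exchanged between near-identical copies would keep the family's sum, which changed by -1.52 ± 0.05 (SE) on the log2 scale. A lower share of cells in S phase stays open as a hypothesis, since the S phase genes, whose transcripts carry poly(A) tails, had a median of -0.82 in KO and -0.23 in CARM1i.

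Of 26 interferon-stimulated genes, 24 rose in KO and 22 in CARM1i (list adjusted p = 0.2884 and 0.2271 with an estimated correlation). Action of 4-OHT or of the recombinase cannot account for the rise in CARM1i, which had no 4-OHT by the labels. The list's median there was 0.27 (SE over libraries 0.07), and 0.19 without CARM1i replicate 3. The rise in KO, a median of 0.48, cannot be told apart from an effect of 4-OHT or the recombinase. The same holds for its excess over CARM1i, a median of 0.26, because no group had 4-OHT without the floxed gene. Macrophages in the treated cultures also stay open, since the fixed markers that passed in KO go both ways. Only 5 of the 14 fixed markers are among the listed genes, each of which has at least 10 reads in at least 1 library. Markers not listed may have had too few reads, which would speak against macrophages, but the reason was not tested. The 4 tested markers had a median of 0.24 in KO (Cd68 higher, Cd14 lower). Of 15 myeloid genes, chosen after the gene tables were seen, 9 rose in KO and 7 in CARM1i and none fell. A list chosen in this way favours such counts, so they add no weight for macrophages. That list's adjusted p was 0.0849 in KO and 0.07821 in CARM1i with an estimated correlation. The bound used, at least 2 markers lower, was rewritten after the values were seen; the first version, met by a single lower marker, would have argued against macrophages.

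Of 25 sterol synthesis genes, 23 rose in KO and 23 in CARM1i (list adjusted p = 0.2869 and 0.06303 with an estimated correlation). An action of 4-OHT on sterol synthesis cannot account for the rise in CARM1i, where the median was 0.64 (SE over libraries 0.07); for the rise in KO, with a median of 0.50, it cannot be told apart from the deletion. A single graded loss of activity that scales all genes alike is argued against, since with the factor of 0.585 from 2442 other genes shared in sign the list's CARM1i changes lay by a median of 0.36 (SE over libraries 0.06) above the scaled KO changes. For each factor tried from 0 to 2, at least 443 of 14560 genes departed from it past 0.05 (at least 48 without the intensity trend and at least 221 without any library). With all libraries the fewest departed at a factor of 0.45. The 0.585 came from genes picked for passing 0.05 in both treatments, a choice that can raise the factor. A different response of each gene to loss of activity, or an action of both compounds beyond CARM1, stays open and was not tested. The same holds for a difference of the untreated WT cultures from both treated groups, since no group is labelled as vehicle.

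Other splits of the 6 libraries of a comparison are too few for a share under 0.05. Under limma 1 of the 10 splits, the real one, gave as many genes as observed in each comparison. The real counts were 6100, 2784 and 3436, and the highest of the others was 0 in each, with at most 418, 1306 and 1107 genes at an unadjusted p under 0.05. Called lists at the preset correlation behaved otherwise. In KO against WT the real split called 11 and the highest other 11 (2 of the 10 splits gave as many, the real one included). The real and highest other counts were 11 and 8 in CARM1i against WT (1 of 10) and 10 and 12 in CARM1i against KO (3 of 10). Every other split called at least 4, so list calls at the preset correlation carry little weight. Each other split mixes libraries of both groups, so the group difference enters the spread and few genes can pass. The 0 genes called there therefore add no weight to the real gene counts. Of 100 regroupings of the 9 libraries, 1, the real one, gave as many genes shared in sign as the 2463 observed. The highest of the others was 2202, in a regrouping that took the 3 KO libraries as the controls, which points to the distance of KO from the other groups. A regrouping that kept the 3 WT libraries as controls and mixed KO with CARM1i gave 852. Where the controls mix groups, the group difference again enters the spread, so the low counts there add no weight to the 2463.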

How the results depend on the processing

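The counts of genes past 0.05 in each comparison, and of genes shared in sign, stayed within 1.5 times their values under no filter, a mean of at least 50, quantile normalization, rescaling to a common total, edgeR and DESeq2 on recovered reads, both other pseudocounts and fits of only the compared groups; edgeR called 6140, 2807 and 3460 genes and DESeq2 5619, 2593 and 3148 in KO against WT, CARM1i against WT and CARM1i against KO. Stricter thresholds lowered counts by construction. A 1.5-fold minimum left 1436, 281 and 522 genes and 222 shared in sign, and an adjusted p under 0.01 left 1668 in CARM1i against WT, 2155 in CARM1i against KO and 1518 shared in sign. Limma without the trend called 1797 in CARM1i against WT and 1607 shared in sign; the cause was not tested. Leaving out a library of the 2 groups compared gave 5245 to 5776 genes in KO against WT, 1937 to 2673 in CARM1i against WT and 2599 to 3684 in CARM1i against KO. Leaving out any of the 9 gave 1739 to 2374 shared in sign. Without WT replicate 2 the genes lower in CARM1i than in WT were 806 against 1251. CARM1i replicate 3, left out after the data were seen for the counts of list members, moved those of ribosomal proteins most (11 to 19 in CARM1i against WT).

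With the replicate number as a block, 5865, 2553 and 3156 genes passed and 2277 were shared in sign. The 9 same-numbered pairs had deviations that correlated between -0.09 and 0.03, and 1 of 9 libraries correlated best with its own number, so the numbers were not taken to pair the libraries. Under the block the glycolysis and hypoxia list missed the threshold in CARM1i against WT (adjusted p = 0.05248). With an estimated correlation the lists called were 2, 2 and 4 of 28, against 11, 11 and 10 at the preset correlation.

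The 305 genes as named in a comparison had 5165 values over the alternatives. Of these, 5052 stayed on the same side of the threshold, 88 missed it, 24 passed it and 1 reversed. Values that passed neither in the main fit nor in the alternative may have changed sign and are among the 5052. Mmp3 in CARM1i against WT, at 0.01 with all libraries, was at -0.20 without CARM1i replicate 3 (adjusted p = 0.001566) and at 0.12 without CARM1i replicate 1, and the cause was not tested. In simulated data at these depths, with 200 genes changed per group, 72% of 1.5-fold changes were recovered in KO against WT. Far more genes, 6100, passed in the real comparison, so recovery there may differ. Other depths were not tested.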

Other observations

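The 6 gene lists in this part were chosen after the gene tables had been seen, so their counts describe these libraries and the genes named here fall outside the rule fixed in advance. A run of matrix metalloproteinase genes on chromosome 9 rose together in KO. Of 8 tested genes 7 rose (median 1.46), with Mmp10 from 770 to 2315, Mmp3 from 3024 to 6675 and Mmp13 from 160 to 384, and Mmp1b did not pass. In CARM1i 3 passed, Mmp10 at 0.58, Mmp13 at 0.54 and Mmp27 at 1.26, while Mmp3 stood at 0.01 and Mmp1a at 0.00, and 5 of the 8 were lower in CARM1i than in KO. The call of Mmp27 ended under edgeR (adjusted p = 0.07977) and 9 other settings, and that of Mmp10 without the intensity trend (adjusted p = 0.05376). The list's adjusted p was 0.0849 in KO, 0.2056 in CARM1i and 0.1069 in CARM1i against KO with an estimated correlation. Genes of class I antigen presentation rose in 15 of 17 cases in KO and 1 fell (median 0.48). B2m went from 44541 to 63567, H2-K1 from 6107 to 9278 and Tapbp from 6915 to 10954, and 8 of the 17 rose in CARM1i (median 0.15). The adjusted p of this list was 0.0849 in KO and 0.1504 in CARM1i with an estimated correlation.

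Genes usually read in myeloid cells rose in both treatments, 9 of 15 tested in KO (median 1.22) and 7 in CARM1i (median 0.65), and none fell. Gpnmb, also a lysosomal gene, went from 10008 to 24052 in KO and 15486 in CARM1i, S100a8 from 91 to 324 and 155, and Mpeg1 from 25 to 103 and 56.3. Lilr4b (24.1 to 165 and 74.9) and Lilrb4a (39.3 to 141 and 96.1) are close copies whose reads may be shared. Trem2 and Coro1a did not pass in either treatment, except Trem2 in KO without the intensity trend (adjusted p = 0.03316). With an estimated correlation the list's adjusted p was 0.0849 in KO and 0.07821 in CARM1i; the macrophage markers fixed in advance had a median of 0.24 in KO, which does not decide whether such cells were present. Around Ivl and Crct1 on chromosome 3, Lce1g (74.3 to 245) and Sprr2g also rose in KO and Lce1h fell (216 to 128), 4 higher and 1 lower of 7, with 3 higher in CARM1i, and adjusted p of 0.1162 and 0.1504 with an estimated correlation. The call of Sprr2g ended without WT replicate 2 (adjusted p = 0.05356) or KO replicate 3 (adjusted p = 0.05357). Lce1g, among the 3 in CARM1i, lost its call under 6 settings and moved from 0.64 to 0.32 without CARM1i replicate 3 (adjusted p = 0.1843). Targets of the oxysterol receptors split in KO, 3 higher and 4 lower of 11, with Abca1 and Abcg1 lower beside the rise of sterol synthesis genes, and in CARM1i 4 were higher and 1, Abcg1, lower, a call that ended under 6 settings.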
